A study of Mus musculus with 34 samples.

How the data were processed

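The RNA sequencing values are whole-number read counts per Ensembl gene, in 6 tables, exon and intron for each of 3 library types. Per the labels, the authors aligned reads with STAR and counted them with featureCounts on mm9 and BDGP5 (Drosophila), and named DESeq2; no versions are given in the sources used here, nor how introns, strand or multi-mapping reads were handled. The chromatin tables have the unit other in the record of units made here, since the prefix Chr. of their columns is read there as a chromosome, and hold, as deposited, raw read counts by their values. The labels describe a Drosophila S2 RNA spike-in; the tables hold 0 Drosophila genes, so no spike-in scaling was used here. The iCLIP files hold a signed whole-number score per base as deposited by the authors, whose sign gives the strand and whose size was read as the number of crosslink counts; the notes name Bowtie 0.12.7 and mm9, and whether random barcodes were collapsed is not given in the sources used here.

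Of 37602 gene IDs in the exon tables and 24503 in the intron tables, 32666 of the former were matched to a symbol. Genes needed a mean count of 50 or more. No condition was replicated within a library type, so the time courses, mock against 0 h, RNase A against mock and pla-B against DMSO were given as ratios of counts over the table total, with a pseudocount of 0.5 and exact 95% intervals. These intervals cover counting error only, since reads without stated molecular identifiers are not independent molecules. A gene was counted as lower or higher at 2-fold. The median of each list with at least 5 measured members was placed among 10000 random lists matched on mean count in 20 bins. Exact Clopper-Pearson 95% intervals of shares of single libraries reached at most 0.0264 percentage points from the value for intron shares (0.111 after RNase A), 0.0161 for Rn7sk shares (0.0296 after RNase A) and 0.0262 for crosslink shares.

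Differences were tested with edgeR 4.0.16 (TMM, quasi-likelihood, 2-sided, Benjamini-Hochberg adjusted p under 0.05). Flavopiridol against triptolide had time as a block (6 libraries), and chromatin against whole-cell poly(A)+ RNA and chromatin total against poly(A)+ RNA had condition as a block (16 libraries each). No combination of time and inhibitor, or of condition and library type, was replicated. These p-values therefore set a difference against its variation between times or conditions, not between replicates. The sources of that variation may be technical. Crosslink counts were summed in 10 kb windows per strand, with a summed count of 30 or more. P-TEFb was tested against LARP7 and against the lone input, which was assumed to vary like the replicated groups. Positions are 1-based mm9. GRCm38 gene records gave gene lengths and neighbours only.

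Named genes followed a rule: in ratios, the 5 largest rises and falls (mean over the 3 times, same direction in all 3) among genes with a mean count of 200 or more; in tests, the 6 highest and 6 lowest past the threshold with that mean; in both, the 3 members of each list with the highest counts, and Rn7sk, Hexim1, Larp7, Cdk9, Ccnt1, Myc, Pou5f1, Malat1 and Neat1. Windows were the 5 with the largest share per group and the 5 highest and 5 lowest by fold (summed count of 100 or more without a test). Gene models without a symbol of their own were passed over. The 20 lists were pluripotency, immediate early and other short-lived mRNAs, p53 targets, 7SK complex and P-TEFb, Pol II subunits and general transcription factors, Polycomb and other chromatin regulators, glycolysis, long noncoding RNAs, Pol III and small nuclear RNAs, polyadenylated intronless or intron-poor genes, splicing factors, detained-intron genes, heat shock and stress chaperones, lineage markers, fibroblast markers, 2-cell-like genes, mitochondrially encoded genes, cytosolic ribosomal proteins, replication-dependent histones, and snoRNA and scaRNA genes. Lists, rule, tests and all other settings except those named below as added were chosen before the data were examined.

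Alternatives were median-of-ratios scaling, table totals, DESeq2 1.42.0, limma-voom (limma 3.58.1), no count minimum or a mean of 200, a pseudocount of 5, a fold limit of 3, no block, 1 kb and 100 kb windows, distinct positions in place of counts, the replicate number as a block, and leaving out each time, condition or replicate. Thinning of the libraries and the intron to exon ratio within genes were added after the data were seen. The tests were tested on simulated data with known changes. At 4-fold they recovered 92% of changed genes for flavopiridol against triptolide in introns and 100% in the other RNA tests, with 3.31 to 11.6% false calls; at 2-fold the intron test recovered 28%. The iCLIP test recovered 48% at 4-fold and 80% at 8-fold, with 4 false calls of 119. Counting intervals covered 95.4 and 95.5% of simulated values. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.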

Results

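The series measured RNA in E14 mouse embryonic stem cells in 34 samples, of which 26 were RNA sequencing libraries and 8 were iCLIP libraries. Chromatin total RNA, depleted of ribosomal RNA, had 9 libraries, poly(A)+ RNA of the chromatin fraction had 8, and poly(A)+ RNA of whole cells had 9. Cells were untreated (0 h), treated for 1, 3 or 9 h with 10 µM flavopiridol, which inhibits the P-TEFb kinase CDK9, or with 10 µM triptolide, which inhibits the TFIIH helicase XPB, or permeabilised with 0.05% Tween-20 and then mock-treated or digested with RNase A at 1 µg/µl for 30 min. Each RNA condition had 1 library per library type, and RNase A had none in chromatin poly(A)+ RNA. Exon counts per library, with M for mega, totalled 8.02 to 33.4 M in chromatin total RNA apart from the RNase A library (0.460 M), 17.5 to 38.6 M in chromatin poly(A)+ RNA and 13.5 to 52.8 M in whole-cell poly(A)+ RNA. Intron counts of chromatin total RNA totalled 3.06 to 16.0 M, and 0.228 M after RNase A. iCLIP, which maps the bases at which a protein is UV-crosslinked to RNA, covered the 7SK-binding protein LARP7 (2 replicates), P-TEFb (3 replicates), P-TEFb in cells given 0.1% DMSO or 1 µM of the splicing inhibitor pladienolide B (pla-B) for 6 h (1 library each) and the P-TEFb input (1 library). These libraries held 133418 to 1821870 crosslink counts.

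The inhibitor time courses followed which RNAs of each class persisted once RNA polymerase II was blocked. In whole-cell poly(A)+ RNA, immediate early and other short-lived mRNAs had the lowest levels of all lists at 1 h and 3 h. Their median log2 ratio to 0 h over 28 measured genes was -2.34 after 1 h, -4.90 after 3 h and -4.40 after 9 h of flavopiridol, and -2.24, -4.61 and -5.72 under triptolide. At 9 h all 28 stood at least 2-fold below 0 h under either inhibitor. Myc, a growth-promoting transcription factor, stood at 0.235, 0.0234 and 0.0167 of its 0 h level after 1, 3 and 9 h of flavopiridol and at 0.307, 0.0318 and 0.00738 under triptolide. Pou5f1, the central pluripotency factor, stood at 1.70-fold (log2 0.76, 95% counting interval 0.74 to 0.78) and 1.62-fold (log2 0.70, 0.68 to 0.71) of its 0 h share at 9 h.

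The named transcripts lowest under flavopiridol were Chac1, a glutathione-degrading enzyme, Dusp6, an ERK phosphatase, Txnip, a thioredoxin inhibitor, Trib1 and Ccn1. Txnip was at 0.0421, 0.0120 and 0.0108 of 0 h, Dusp6 at 0.111, 0.0101 and 0.00301, and Ccn1 at 0.0467, 0.00731 and 0.0350. Chac1 went from 1333 counts at 0 h to 86, 10 and 1, and Trib1 from 819 to 86, 8 and 2. Under triptolide Egr1, an immediate early transcription factor, was at 0.0340, 0.0118 and 0.00855 of 0 h, and the others at the bottom were Chac1 (118, 0 and 6 counts), Ccn1, Txnip and Gadd45g. At the other end stood the ribosomal protein gene Rpl37a at 2.97, 3.58 and 1.63-fold under flavopiridol and 2.89, 1.24 and 4.69-fold under triptolide, and the imprinted noncoding RNA Meg3 at 1.48, 1.92 and 2.48-fold under flavopiridol. Ybx2, Vcp-rs and Cnih2 followed under flavopiridol, and Psme2b, Ttc25, Arl5c and Fbxo36 under triptolide. The values of Rpl37a did not follow the order of the times. Rpl37a also moved without an inhibitor, to 0.409 of 0 h in the mock library of chromatin poly(A)+ RNA (5669 against 16127 counts).

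By list, pluripotency genes (28 measured) had a whole-cell median of -1.42 at 9 h of flavopiridol and -1.78 at 9 h of triptolide, with 17 members at least 2-fold lower under each. For p53 targets (20) the medians were -1.81 and -2.31, with 15 members lower under each. Polyadenylated short intronless or intron-poor genes (13) stood at -3.81 and -4.40 and all 13 were lower. Components of the 7SK complex and P-TEFb (19) stood at -1.36 and -1.78, with 13 and 14 lower. Within that list Hexim1, which holds P-TEFb inactive, was at 0.0394 and 0.0475 of 0 h, the P-TEFb cyclin Ccnt1 at 0.149 and 0.0996, Cdk9 at 0.338 and 0.186, and Larp7 at 1.27 and 1.32-fold. Medians were also negative for Polycomb and other chromatin regulators (30 genes, -0.99 and -1.35), heat shock and stress chaperones (16, -1.10 and -1.27), detained-intron genes (18, -0.69 and -1.13), long noncoding RNAs (11, -1.61 and -1.55), markers of differentiated lineages (14, -2.04 and -2.04), the 2 measured 2-cell-like genes (-0.91 and -0.79) and the 4 measured snoRNA genes (-0.68 and -1.09). They were positive for cytosolic ribosomal proteins (88, 0.69 and 0.80), glycolysis (13, 0.62 and 0.65) and fibroblast markers (8, 0.46 and 0.14). Pol II subunits and general transcription factors (31, -0.19 and -0.23) and splicing factors (26, -0.26 and -0.24) turned positive under median-of-ratios scaling, at 0.34 and 0.39 and at 0.27 and 0.37. Replication-dependent histones (14) stood at 0.25 and -0.05, the second value becoming 0.56 under that scaling. Among 10000 random lists matched on mean count, the immediate early median had percentile 0 at every time, and the ribosomal median percentile 100 at 3 h and 9 h. All 37 mitochondrially encoded genes were at 0 counts in every library.

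The number of genes at least 2-fold below 0 h in whole-cell RNA was 467, 2776 and 4660 of 12479 under flavopiridol and 350, 2094 and 4998 under triptolide. At 9 h, 146 and 202 genes stood at least 2-fold above. Median-of-ratios scaling shifted all log2 ratios at 9 h by 0.53 and 0.61 and gave 3161 lower with 1708 higher for flavopiridol and 3472 lower with 2117 higher for triptolide. All ratios here are relative to the library's table total, with no test, since each condition had 1 library and no Drosophila spike-in counts were used here. The mock-treated library had 37 genes lower and 54 higher by the same limit.

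**Figure D1:**
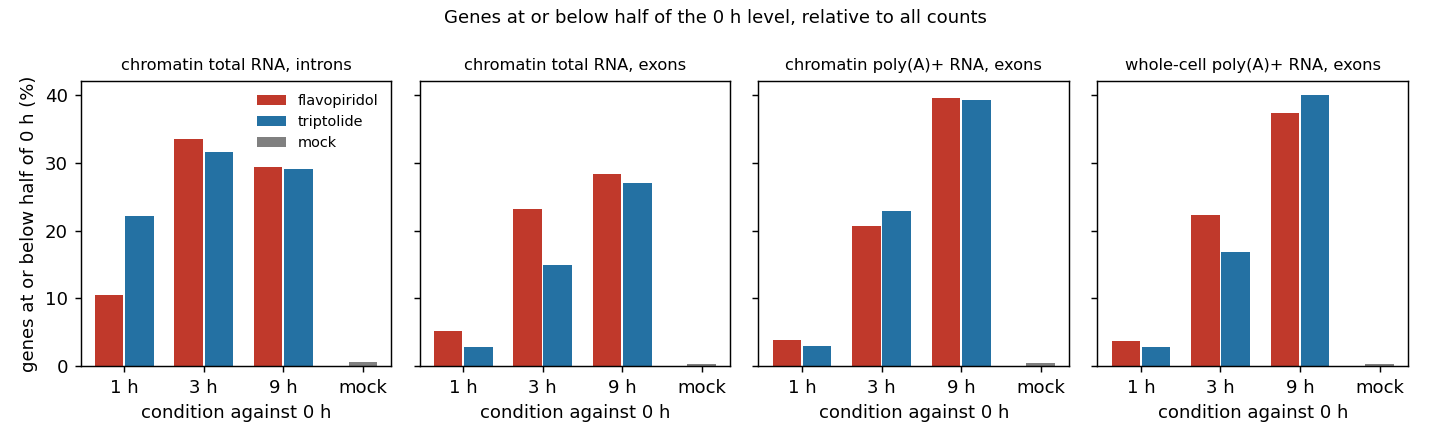
Percent of measured genes at least 2-fold below their 0 h level (vertical axes) after 1, 3 and 9 h of flavopiridol or triptolide and in mock-treated cells, in 4 panels for whole-cell poly(A)+ exons, chromatin poly(A)+ exons, chromatin total exons and chromatin total introns. Each bar is 1 library against the 0 h library of its type, and the number of genes is largest at 9 h in all 3 exon readouts.

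In chromatin poly(A)+ RNA, immediate early genes had medians of -2.38, -4.59 and -4.39 under flavopiridol and -2.17, -4.71 and -5.83 under triptolide, with all 28 measured members lower at 9 h. Klf2, a pluripotency transcription factor, stood at 0.311, 0.0194 and 0.00463 of 0 h under flavopiridol, beside Chac1, Txnip, Dusp6 and Ccn1 as the lowest. Triptolide had Ccn1, Egr1, Chac1, Dusp1 and Txnip as the lowest. Rn7sk went from 91 counts to 1801 and 2003 at 9 h (31.4 and 40.1-fold). Lars2, the mitochondrial leucyl-tRNA synthetase, stood at 1.27, 1.64 and 6.23-fold under flavopiridol and 1.69, 3.12 and 5.64-fold under triptolide. Nckap1l, Med16 and Gatm (flavopiridol) and the 5S ribosomal RNA n-R5s88, Nckap1l and Sarnp (triptolide) followed. Histones (10) stood at 1.03 at 9 h of flavopiridol and -0.72 at 9 h of triptolide. At 9 h 4899 and 4865 of 12377 genes were at least 2-fold lower, with 310 and 279 at least 2-fold higher, and median-of-ratios scaling, a shift of 0.60 for both, gave 3255 with 2113 and 3412 with 2237. Across 12167 genes, which are not independent replicates, log2 ratios in chromatin and whole-cell poly(A)+ RNA correlated with Pearson r = 0.944 and Spearman rho = 0.938 for flavopiridol at 9 h and r = 0.953 and rho = 0.937 for triptolide, against r = 0.795 and 0.764 (rho = 0.728 and 0.592) at 1 h and r = 0.591 (rho = 0.580) for mock, and at 9 h 4130 and 4342 genes were at least 2-fold lower in both.

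In the exon counts of chromatin total RNA Rn7sk, the 7SK RNA that binds and inhibits P-TEFb, took 0.458% of the counts at 0 h and 1.31, 2.22 and 5.26% after 1, 3 and 9 h of flavopiridol, and 1.96, 3.15 and 5.73% under triptolide. Relative to 0 h it stood at 11.5-fold (log2 3.52, 95% counting interval 3.51 to 3.53) and 12.5-fold (log2 3.64, 3.63 to 3.66) at 9 h, and at 0.740-fold in mock-treated cells. By the mean log2 ratio over the 3 times Hspd1-ps3 stood above it under flavopiridol (3.93 against 2.44), and Grcc10, Cox6a1, a cytochrome oxidase subunit, and the U8 snoRNA Snord118 were also among the highest, with Grcc10 at 1.43, 4.07 and 11.4-fold and Snord118 at 1.60, 8.53 and 2.95-fold. Triptolide had Scarna6, which guides modification of spliceosomal RNA, at log2 ratios of 1.32, 1.64 and 2.64, then Arl5c, Snord13 and Rps27a-ps2. Lowest under flavopiridol were Txnip, Pdik1l, Xist, the noncoding RNA of X inactivation, Klf6 and Dusp6, with Xist at 0.154, 0.0199 and 0.0244. Under triptolide they were Txnip, Ccn1, Dusp1, Klf6 and Ccnl1, a cyclin tied to splicing, which stood at 0.127, 0.0376 and 0.0220. Malat1, a nuclear noncoding RNA, stood at 1.41-fold at 9 h of flavopiridol and 0.681-fold at 9 h of triptolide, Neat1 at 0.119 and 0.218, Hexim1 at 0.193 and 0.151, Ccnt1 at 0.186 and 0.184, Myc at 0.0500 and 0.0319, and Pou5f1 at 2.16 and 2.08-fold.

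In the same readout immediate early genes (26) had medians of -1.44, -2.95 and -2.14 under flavopiridol and -1.47, -3.87 and -4.95 under triptolide, and intronless genes (13) ended at -1.43 and -2.84. Cytosolic ribosomal proteins (86) ended at 1.30 and 1.12, with 74 and 56 members at least 2-fold higher, and glycolysis genes (13) at 1.16 and 0.95. Detained-intron genes (18) ended at -0.84 and -1.40. Replication-dependent histones (43) stood at -0.89, -1.49 and -0.64 under flavopiridol and 0.07, -0.34 and -1.37 under triptolide. For snoRNA and scaRNA genes (33) the medians were -0.48, 1.00 and 0.13 against 0.35, 0.60 and 0.89, and for Pol III and small nuclear RNAs (9) they were 0.10, 0.49 and 0.65 against 0.16, 0.34 and 0.80. At 9 h 3234 and 3078 of 11402 genes were at least 2-fold lower and 855 and 571 higher, and median-of-ratios scaling (shifts of 0.26 and 0.30) gave 2583 with 1608 and 2353 with 1356. A gene model without a symbol in the tables used here held 5.50% of exon counts at 0 h and 8.08% at 3 h of flavopiridol.

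**Figure D2:**
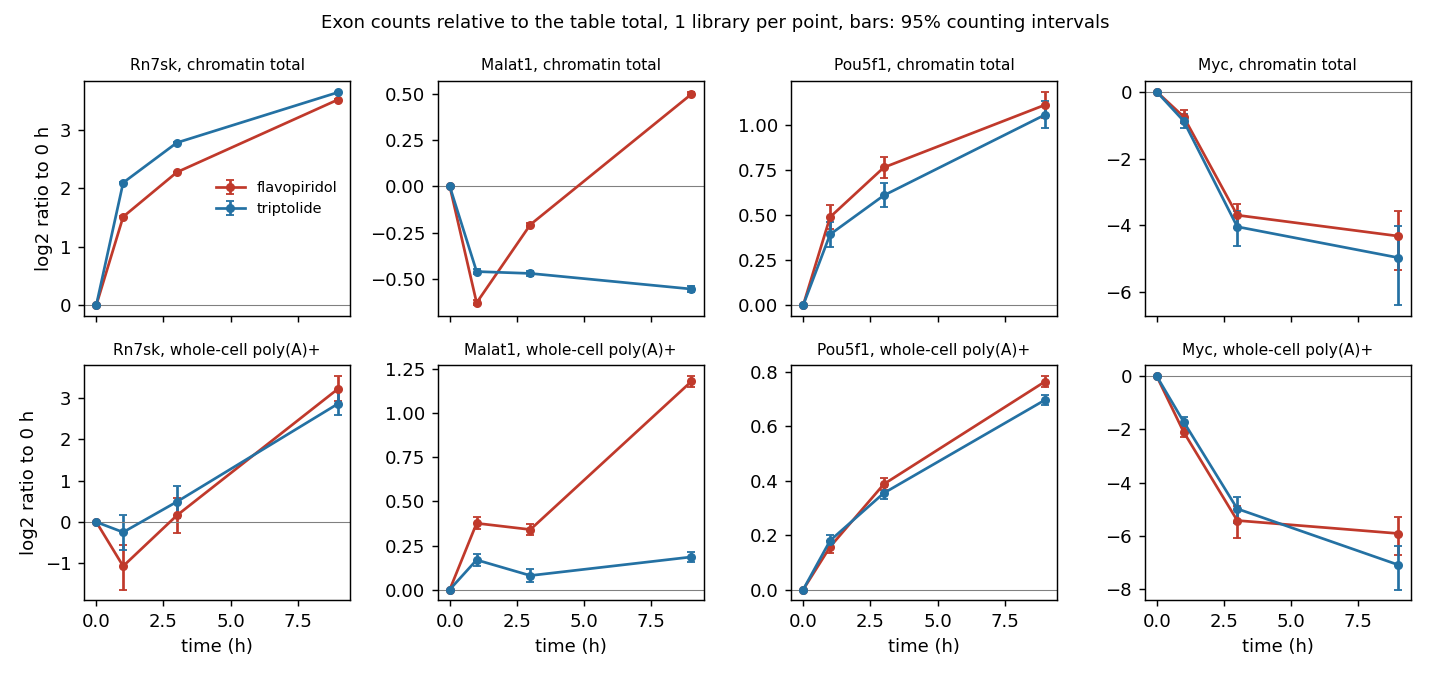
Log2 ratio to 0 h (vertical axes, scales differ between panels) against hours of treatment for Rn7sk, Malat1, Pou5f1 and Myc in exon counts of chromatin total RNA (top) and whole-cell poly(A)+ RNA (bottom), with flavopiridol and triptolide as separate lines. Points are single libraries and bars are 95% counting intervals, and in chromatin total RNA Rn7sk reached 3.52 under flavopiridol and 3.64 under triptolide.

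Intron counts, which mostly come from unspliced RNA, made up 41.7% of exon plus intron counts in chromatin total RNA at 0 h and 42.8% in mock-treated cells. They made up 28.8, 26.1 and 26.4% after 1, 3 and 9 h of flavopiridol and 28.9, 25.7 and 28.5% under triptolide. In poly(A)+ libraries the share stayed between 20.7 and 23.1%. Within genes the intron to exon ratio was lower than at 0 h in 95.1% of 8851 genes after 1 h of flavopiridol and in 93.5% after 1 h of triptolide, with median log2 changes of -0.80 and -0.99, against 0.09 in mock-treated cells. After 1 h of triptolide the ratio was also lower in 84.7% of 8953 genes in chromatin poly(A)+ RNA (median change -0.26). In whole-cell poly(A)+ RNA it was lower in 77.2% of 9285 genes (-0.15). After 1 h of flavopiridol these shares were 57.2 and 36.3%. The intron to exon ratio needs no scaling and was added after the data were seen.

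**Figure D3:**
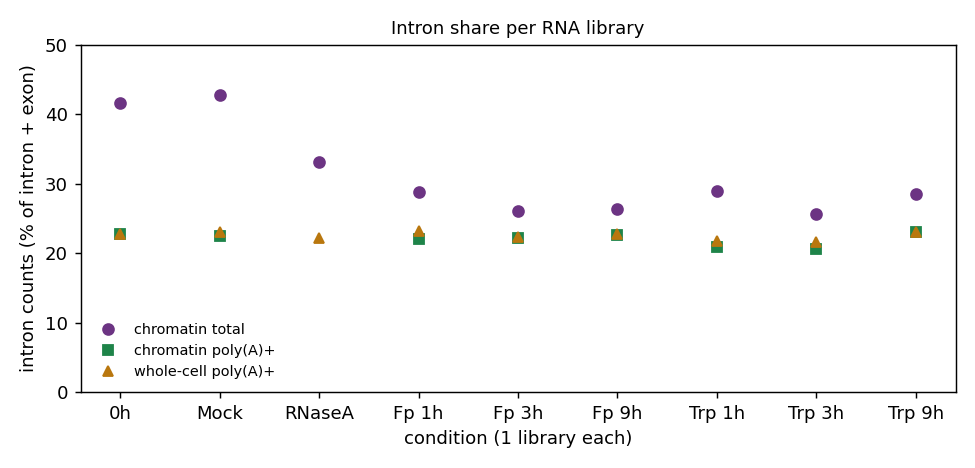
Intron counts as a percent of exon plus intron counts (vertical axis, 0 to 50%) for each library by library type. Each point is 1 library, and chromatin total RNA lies at 41.7% at 0 h and between 25.7 and 28.9% under the inhibitors, while the poly(A)+ libraries lie between 20.7 and 23.1%.

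Relative to the total of intron counts, the lowest introns under flavopiridol were those of Hpgds, a prostaglandin D synthase, at 0.0416, 0.0261 and 0.0129 of 0 h (842 counts at 0 h and 2 at 9 h, where the log2 interval is -9.65 to -4.74), Slco1c1, a hormone transporter, Basp1 (0.205, 0.0828 and 0.0747), Svopl and Kbtbd2. Triptolide had Srfbp1, Ccnl1 (0.0564, 0.0232 and 0.0180), Dtl, a ubiquitin ligase receptor (0.0615, 0.0158 and 0.0308), Zfp367 and Cep152, a centrosome protein. Highest under flavopiridol were Rps19bp1 (7.41, 40.9 and 121-fold), Znrd1as, Alkbh4, Npl and Zc3h7a (3.23, 14.4 and 5.29-fold). Triptolide had Rps19bp1 (13.7, 51.7 and 118-fold), Arhgap15 (1.96, 108 and 112-fold), Dpys (7.09, 26.4 and 24.2-fold), Cadps, a secretion factor (1.52, 31.4 and 82.3-fold), and Tprg with 3 counts at 0 h and 2, 2076 and 184 counts after it (log2 interval at 9 h 6.43 to 10.29). Immediate early introns (9) had medians of -1.98, -2.47 and -1.54 under flavopiridol and -2.16, -3.71 and -3.61 under triptolide, and introns of p53 targets (15) -0.58, -0.71 and -0.39 against -0.78, -1.59 and -1.51. Introns of ribosomal protein genes (77) ended at 1.54 and 0.89, of glycolysis genes (13) at 1.51 and 1.13, and of heat shock genes (13) at 0.99 and 0.51. At 9 h 3028 and 3000 of 10317 genes were at least 2-fold lower and 1924 and 1915 higher, and median-of-ratios scaling (shifts of 0.20 and 0.26) gave 2520 with 2378 and 2430 with 2551. GRCm38 places other genes over Svopl, Kbtbd2, Dtl, Cep152, Zc3h7a, Arhgap15, Dpys and Cadps, so their intron counts may include reads of those. It also places snoRNA genes over the ribosomal protein genes Rpl13a, Rps3 and Rpsa and over the heat shock gene Hspa8. Intron medians of these lists may thus include snoRNA reads, and list members not named were not checked.

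Flavopiridol and triptolide were compared at the same dose and times, which asks whether blocking P-TEFb and blocking TFIIH left different RNAs. In introns of chromatin total RNA 466 genes were higher and 752 lower under flavopiridol. Ccnl1 introns were 9.59-fold higher (log2 3.26 ± 0.47, SE, adjusted p = 0.0119 from edgeR), those of the SR protein kinase Clk4 6.48-fold (2.70 ± 0.37, 0.0114), those of Dtl 5.92-fold (2.57 ± 0.31, 0.00851), and those of Uri1, Ube2e3 and Ranbp9 5.57, 5.47 and 5.07-fold. Mdm2, the p53 ubiquitin ligase, was 4.33-fold higher (2.11 ± 0.45, 0.0318). Lowest were the transporter gene Svopl (-6.13 ± 0.37, 0.00406), the integrin Itgb6 (-6.12 ± 0.93, 0.0136), Tprg (-5.78 ± 1.44, 0.0480), Ism1 (-5.56 ± 0.45, 0.00441), the kinase Pak7 (-5.56 ± 0.90, 0.0160) and Cadps (-5.54 ± 1.17, 0.0307). Each of these 13 genes had its direction at 3 of 3 times.

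Of the lists, 6 of 18 detained-intron genes were higher under flavopiridol (7 when adjusted over the list alone), as were 5 of 25 splicing factors (8 adjusted over the list alone), 4 of 14 p53 targets (4), 3 of 28 Polycomb and other chromatin regulators (4), 6 of 77 ribosomal protein genes (3), 2 of 27 Pol II and general factor genes, 1 of 17 pluripotency genes (1), 1 of 17 genes of the 7SK complex and P-TEFb and 1 of 12 glycolysis genes. Among 11 long noncoding RNAs 1 was higher and 1 lower, and 1 of 7 lineage markers was lower. No immediate early (4 measured, 2 higher when adjusted over the list alone), heat shock (9), fibroblast (5, 1 higher adjusted over the list alone), histone (4) or intronless gene (2) passed. Cdk9 (log2 0.63, adjusted p = 0.142), Larp7 (0.68, 0.139), Ccnt1 (-0.51, 0.179) and Malat1 (0.29, 0.499) did not pass. The test was 2-sided edgeR with time as a block over 9633 genes, of which 2928 had an unadjusted p under 0.05. Without the 3 h pair 0 genes passed in edgeR, with 1545 at an unadjusted p under 0.05; without the 9 h pair the calls for Mdm2, Pak7 and Cadps ended. Without time as a block 336 genes passed, Mdm2, Dtl and Tprg not among them, and DESeq2 and limma-voom called 1740 and 1542. GRCm38 places BC049762 over Clk4, Ints7 over Dtl, Nol7 over Ranbp9 and gene models over Ube2e3, Ranbp9, Svopl, Itgb6, Pak7 and Cadps, so their intron counts may include reads of those genes.

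For exon counts of poly(A)+ RNA, few genes passed the test of a difference shared by the 3 times. A difference confined to 1 time adds to the spread in this test, so few calls do not show that few genes differ. In chromatin poly(A)+ RNA the pseudogene Hspd1-ps3 was 6.95-fold higher under flavopiridol (log2 2.80 ± 0.11, adjusted p = 0.00240) and the small nucleolar host RNA Snhg17 3.12-fold higher (1.64 ± 0.14, 0.0482). The other 3 of the 5 genes, named after their values were seen, were Stac3 (-3.10 ± 0.21, 0.0293) and the gene models Gm10800, lower, and 1 without a symbol, higher. All 5 had their direction at 3 of 3 times. Hspd1-ps3 also moved without an inhibitor, to 0.144 of 0 h in the mock library of chromatin poly(A)+ RNA (228 against 1845 counts). In whole-cell RNA the 1 call, also named after its values were seen, was Egr2, an immediate early transcription factor, lower under flavopiridol (-6.05 ± 0.32, 0.0341, lower at 3 of 3 times). Egr2 was also the 1 immediate early gene of 23 to pass there (1 adjusted over the list alone), and no other list had a member past the threshold in whole cells, nor any list in chromatin. Adjusted over the list alone, 3 of 18 detained-intron genes were higher and 1 lower in chromatin and 2 higher and 1 lower in whole cells. So were both measured Pol III RNAs, lower in chromatin, and in whole cells 1 splicing factor, 1 fibroblast marker and 1 histone, higher. Of 12075 and 12184 genes tested, 904 and 852 had an unadjusted p under 0.05, and DESeq2 called 56 and 53 and limma-voom 5 and 0. Without the 3 h pair edgeR called 0 in both readouts, with 179 and 196 genes at an unadjusted p under 0.05, and without time as a block 0, with 122 and 99. Scaling by table totals left 2 and 0 calls, and Snhg17 passed under neither that nor median-of-ratios scaling. Without the 1 h pair it called 105 and 131 genes, and without the 9 h pair 341 and 13.

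Mock treatment asked what permeabilisation and incubation alone changed. Replication-dependent histones stood out in chromatin total RNA, with a median log2 ratio to 0 h of 0.66 over 43 genes and 8 of them at least 2-fold higher. Hist1h4j was at 2.86-fold (log2 1.51, 95% counting interval 1.36 to 1.68), followed by Hist1h2ad, Hist1h4n, Hist1h2ah and Hist1h2ag. Vcp-rs stood at 0.127, and Itga1, the Wnt effector Lef1, Cysltr1 and Nefh at 0.416 to 0.454. In whole-cell RNA the noncoding RNA Neat1 stood at 2.73-fold, the stress gene Nupr1 at 2.38-fold, Snhg20 at 2.83-fold, Vcp-rs at 3.20-fold and Got1l1 at 2.37-fold, while Hspd1-ps3 was at 0.0870, Ntn1, a guidance cue, at 0.350, the mesoderm factor T at 0.382 and Lef1 at 0.416. Chromatin poly(A)+ RNA had Nupr1 at 2.83-fold, Neat1 at 2.41-fold, Hspb2, Txnip at 1.95-fold and Acss1 as highest, and Hspd1-ps3, n-R5s88, Vcp-rs, Ntn1 and Rpl37a as lowest. Among introns Dnaaf2 was at 25.8-fold, followed by Fkbp6, Apoe, Hist1h2bc and Tdgf1, with Svopl, Tenm1, Smndc1, Sbspon and Zfp367 lowest, and GRCm38 places other genes over Dnaaf2, Svopl and Tenm1. At least 2-fold lower and higher were 57 and 45 genes for introns, 44 and 57 for chromatin total exons and 63 and 31 for chromatin poly(A)+ RNA. Median-of-ratios scaling shifted the chromatin total ratios by -0.11 for introns and -0.12 for exons and gave 88 with 26 and 63 with 28.

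RNase A digestion of permeabilised cells, set against mock, addressed which RNAs took a smaller or larger share of chromatin RNA afterwards. The ratios are relative to each library's table total. A rise is thus a larger share of the RNA that was left, and the amount of an RNA removed cannot be read from these ratios. In exon counts of chromatin total RNA, snoRNA and scaRNA genes had a median log2 ratio of -2.71 and 29 of 33 were at least 2-fold lower, and histones (43) stood at -1.66, at percentile 0.370 of random lists matched on counts (random median -0.68). Ribosomal protein genes (86) stood at -1.60, where such lists had -1.17 (percentile 3.93). Detained-intron genes (18) stood at 1.25, at percentile 100 of random lists, and intronless genes (13) at 0.74. Malat1 was at 4.02-fold (log2 2.01, 95% counting interval 1.98 to 2.03), Rn7sk at 3.04-fold (1.60, 1.56 to 1.65), Hexim1 at 5.93-fold, Myc at 5.33-fold and Larp7 at 4.52-fold, against 0.606 for Pou5f1 and 0.243 for Neat1. Lars2 was at 137-fold and Gripap1, Inf2, Tpm2 and Safb2 at 25.0 to 27.9-fold. Rps15a, Zfp729b, Tmem106b, Tmed5 and Tm9sf2 had 0 counts after RNase A against 5247, 3954, 3179, 3129 and 3056 in mock. Among introns Il31ra had 4929 counts against 182 in the far deeper mock library, and Catsperg1, Mup6 and Pcgf2 were also among the highest, while Cd247, Tmed5, Ube3a and Ankrd10 had 0 counts against 14569, 7100, 5319 and 4754 and Dnaaf2 had 1 against 15460. GRCm38 places Pou2f1 over Cd247, Snhg14 over Ube3a, Mir7238 over Ankrd10 and 9330151L19Rik over Dnaaf2, so those intron counts may include reads of other genes.

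With 0.460 M exon and 0.228 M intron counts, the RNase A chromatin library decided little for single genes. Genes of high mock count also reached 0, among them Rps15a and Cd247, and Il31ra alone held 4929 of the intron counts. Whether the enzyme or the small library caused this was not tested, and the counting intervals do not cover it. Lower and higher by 2-fold were 4831 and 1976 exon genes and 3939 and 2099 intron genes, but 2248 and 3205, and 1390 and 3950, with a pseudocount of 5 in place of 0.5, which turns the balance. Median-of-ratios scaling (shifts of 0.45 and 0.30) gave 3868 with 2826 and 3328 with 2670. In whole-cell poly(A)+ RNA, by contrast, 24 genes were lower and 25 higher (19 and 30 under median-of-ratios scaling, 11 and 36 with a pseudocount of 5), with Hspd1-ps3 at 7.13-fold, Rpl37a at 3.44-fold, Rpl23a-ps3, Psme2b and BC005561 highest and Vcp-rs (log2 -1.74), Ube2v1 at 0.397, Rn7sk at 0.479 (14 counts, log2 interval -2.03 to -0.29), Lysmd3 and Amd2 lowest.

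The chromatin and whole-cell poly(A)+ libraries were compared over 8 shared conditions to find polyadenylated RNAs held on chromatin. Gsdme, a pore-forming protein, was 6.11-fold higher in chromatin (log2 2.61 ± 0.19, SE, adjusted p = 2.06e-07), Bod1l 6.07-fold (2.60 ± 0.10, 2.16e-09), the Ro RNA-binding protein gene Trove2 5.30-fold, Usf3 5.10-fold, the transcription factor Foxp1 5.01-fold (2.32 ± 0.10, 7.3e-09) and Nhs 4.94-fold. Lowest were Rps12-ps3 (-1.28), Rps12 (-1.04 ± 0.05, 2.63e-08), Rpl17-ps10, Tdh, the threonine dehydrogenase of mouse stem cells (-0.92), Rps3a2 and the replication nuclease Fen1 (-0.89 ± 0.08). The elongation regulator Aff4 (1.05 ± 0.13, 1.74e-05), fibronectin Fn1 (1.12 ± 0.08) and Hist1h2bc (1.18 ± 0.16) were higher, and Pou5f1 (-0.59 ± 0.05, 6.19e-07) and Rpl13a (-0.68 ± 0.06) lower. Each gene named so far had its direction in 8 of 8 pairs. Rn7sk was 3.16-fold higher (1.66 ± 0.25, 0.000102), Ccnt1 1.36-fold and Larp7 1.16-fold (all 8 of 8 pairs), and Hexim1 (-0.11, 0.186), Cdk9 (-0.05, 0.404) and Neat1 (-0.09, 0.188) did not pass. The Rn7sk difference lay mostly in inhibitor-treated cells. Its share in chromatin and whole cells was 0.000284 and 0.000269% at 0 h and 0.000250 and 0.000224% in mock. At 9 h it was 0.00895 and 0.00251% under flavopiridol and 0.0114 and 0.00196% under triptolide. Rn7sk was far scarcer in poly(A)+ than in total RNA (below), so these counts do not show a poly(A) tail.

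Of 88 cytosolic ribosomal proteins 86 were lower in chromatin and 0 higher (87 lower adjusted over the list alone), as were 19 of 31 Pol II and general factor genes with 2 higher (20 and 2), 14 of 26 splicing factors with 3 higher (14 and 4), 13 of 28 pluripotency genes with 6 higher, 11 of 30 Polycomb and other chromatin regulators with 4 higher (10 and 4) and 5 of 13 glycolysis genes with 1 higher. Higher were 11 of 28 immediate early genes with 0 lower, 7 of 13 intronless genes, 8 of 11 long noncoding RNAs (1 lower adjusted over the list alone), 8 of 9 fibroblast markers with 1 lower, 9 of 15 lineage markers with 1 lower (10 and 1), 11 of 18 detained-intron genes with 5 lower, 8 of 20 p53 targets with 4 lower, 8 of 19 genes of the 7SK complex and P-TEFb with 4 lower and 4 of 16 heat shock genes with 3 lower. Of the smallest lists, 2 of 3 2-cell-like genes were higher (3 adjusted over the list alone), 1 of 2 Pol III RNAs, 1 of 4 snoRNAs, and 1 of 11 histones with 2 lower. Of 12503 genes 3497 were higher and 3725 lower in 2-sided edgeR with condition as a block, and 4264 and 2709 with scaling by table totals. Without the block 1206 passed, 923 higher and 283 lower, and the calls for Pou5f1, Rpl13a, Rn7sk, Ccnt1 and Larp7 were lost.

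Chromatin total and poly(A)+ RNA were compared in the same 8 conditions to find chromatin RNAs that were under-represented after poly(A)+ selection. A higher level in total RNA does not by itself show a missing poly(A) tail, since the library types also differ by preparation. Rn7sk was 1490-fold higher in total RNA (log2 10.54 ± 0.42, SE, adjusted p = 1.51e-09), Scarna10 1180-fold, Rpph1, the RNase P RNA, 972-fold, the telomerase RNA Terc 888-fold (9.79 ± 0.15, 5.13e-12), Scarna2 870-fold and Rmrp 398-fold (8.64 ± 0.25). All 41 measured histones, all 30 snoRNA and scaRNA genes and all 8 Pol III and small nuclear RNAs were higher, with medians of 6.13 for histones and 4.02 for snoRNA genes. Malat1 was 10.3-fold higher (3.37 ± 0.12, 9.77e-10), the DNA demethylase Tet1 7.28-fold, Aff4 3.99-fold, Srrm2 3.66-fold and Polr2a 2.46-fold. Lowest were n-R5s88 (-7.99 ± 0.25, 5.08e-10), Rps27a-ps2, Rps27rt, Sap18b, Rpl39-ps and Rps16-ps2, and Pou5f1 (-1.51 ± 0.06, 2.2e-09), Larp7 (-1.13 ± 0.07) and Bax (-1.86 ± 0.13) were lower. Each of these had its direction in 8 of 8 pairs. The total libraries were depleted of ribosomal RNA, so the place of the ribosomal RNA n-R5s88 says nothing about a poly(A) tail. Cdk9 was lower (-0.65, 0.00125, lower in 7 of 8 pairs), and Hexim1 (-0.38, 0.0662), Myc (0.28, 0.157) and Neat1 (-0.45, 0.0524) did not pass.

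Ribosomal proteins (85 of 87 lower, 0 higher), heat shock genes (12 of 16 lower, 0 higher), glycolysis genes (11 of 13 lower, 1 higher), splicing factors (19 of 26 lower, 5 higher) and Pol II and general factor genes (22 of 31 lower, 6 higher) were mostly lower in total RNA, and of 28 pluripotency genes 13 were lower and 8 higher. More members were higher than lower among Polycomb and other chromatin regulators (15 of 30 higher, 10 lower), long noncoding RNAs (7 of 12 higher, 3 lower, 4 lower adjusted over the list alone), immediate early genes (9 of 28 higher, 8 adjusted over the list alone, 0 lower), intronless genes (3 of 13 higher, 0 lower) and 2-cell-like genes (1 of 3 higher), though in the last 3 lists most members did not pass. The rest split evenly or nearly so, with 8 higher and 7 lower of 20 p53 targets, 7 and 7 of 19 genes of the 7SK complex and P-TEFb, 6 and 7 of 18 detained-intron genes, 4 and 4 of 14 lineage markers and 4 and 4 of 9 fibroblast markers. Counts adjusted over the list alone were the same where none is given. Of 12238 genes 4493 were higher and 5116 lower in 2-sided edgeR with condition as a block.

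Crosslinks of LARP7 and P-TEFb were counted in strand-specific 10 kb windows of mm9, which carry no gene names here. The window on chromosome 17 from 39980001 to 39990000, plus strand, held 9.44% ± 1.82 (SD, n = 2) of LARP7 counts, 2.91% ± 1.95 (SD, n = 3) of P-TEFb counts and 3.13% of input. In single P-TEFb libraries it held 0.689% under DMSO and 0.786% under pla-B. The mitochondrial window from 1 to 10000, plus strand, held 1.12% ± 0.123 of LARP7, 1.43% ± 1.19 of P-TEFb and 1.30% of input counts. On chromosome 19 from 5790001 to 5800000, minus strand, lay 0.395% ± 0.00396 of LARP7, 0.256% ± 0.0860 of P-TEFb and 0.560% of input counts, with 0.133% under DMSO and 0.00850% under pla-B. The next windows were chromosome 17 from 39970001 (plus) and chromosome 2 from 90230001 (minus) for LARP7, with 0.504% ± 0.241 and 0.224% ± 0.107, and for P-TEFb chromosome 2 from 90230001 again, with 0.237% ± 0.218, and chromosome 19 from 5800001 (minus), with 0.163% ± 0.110. That last window held 0.171% of input and chromosome 1 from 162960001 (plus) 0.169%. Chromosome 7 from 140250001 and from 140300001 (minus) held 0.126 and 0.121% under DMSO. Across 7479 windows, which are not independent, log counts correlated with r = 0.838 (rho = 0.818) between the LARP7 replicates, r = 0.478 to 0.641 (rho = 0.433 to 0.616) between the P-TEFb replicates, and r = 0.795 and 0.817 (rho = 0.810 and 0.847) between LARP7 and input. P-TEFb replicate 1 correlated better with LARP7 (r = 0.698 and 0.671) than with P-TEFb replicates 2 and 3 (0.641 and 0.636), and replicate 3 correlated at r = 0.765 with DMSO and 0.282 with input.

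P-TEFb and LARP7 crosslinking differed in 43 of 27502 windows, 27 higher and 16 lower for P-TEFb. Highest by fold were chromosome 5 from 71640001, plus strand (log2 5.74 ± 1.23, SE, adjusted p = 0.0476, with 57, 10 and 2 counts against 1 and 0, each at 1 position, and 53 at 1 position in the input), chromosome 13 from 20750001, minus (3.43 ± 0.71, 0.0396, at 1 or 2 positions per library of either protein), chromosome 8 from 123030001, plus (3.26 ± 0.64, 0.0269), chromosome 4 from 136350001, minus (2.95 ± 0.57, 0.0200), and chromosome 11 from 117190001, plus (2.95 ± 0.49, 0.00555), each higher in 3 of 3 P-TEFb libraries. The last 3 of these passed with distinct positions too (adjusted p = 0.0324, 0.0202 and 0.00660), and the first 2 had too few positions to be tested that way. The chromosome 11 window had 72.5 ± 19.8 (SD, n = 3) library-scaled counts (CPM) for P-TEFb and 8.51 ± 1.55 (SD, n = 2) for LARP7. LARP7 was higher on chromosome 2 from 38880001, plus (139 ± 66.1 against 0.379 ± 0.657 CPM, adjusted p = 9.21e-07), and on chromosome 12 from 103490001, minus (46.2 ± 2.53 CPM against 0 counts, 0.000113), chromosome 11 from 15310001, plus (0.00167), chromosome 15 from 17610001, minus (0.0126), and chromosome 9 from 46430001, minus (0.0140), which all had 0 P-TEFb counts. Of the 16 windows higher for LARP7, 14 had over 5 counts per crosslinked position and 1 was also called with distinct positions, while 24 of the 27 higher for P-TEFb were. DESeq2 called 70 higher and 4 lower. The 2-sided edgeR test had 3136 windows at an unadjusted p under 0.05. It called 13 and 5 windows without LARP7 replicate 1 or 2, with 0 higher for P-TEFb in either, and 285, 327 and 259 without P-TEFb replicate 1, 2 or 3.

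Against the input, 366 windows were higher and 442 lower for P-TEFb of 37302. Among the 5 highest, chromosome 5 from 140320001, plus (log2 7.74 ± 1.40, adjusted p = 0.000536, with 26, 124 and 56 counts at 2, 3 and 2 positions), and chromosome 13 from 37910001, plus (17, 1 and 19 counts against 0 in the input, 0.00124), were higher in 3 of 3 libraries, as was chromosome 2 from 6990001, minus (11, 51 and 13 counts against 0, 0.00164). Chromosome 4 from 120800001 (plus) was higher in 2 of 3 libraries and chromosome 11 from 50180001 (minus) in 1, with 46 counts. Of these 5 windows, chromosome 13 from 37910001 had enough positions to be tested with distinct positions and passed (adjusted p = 0.00467). Lowest were chromosome 2 from 76460001, plus, with 454 input counts, chromosome 16 from 14180001, minus, with 351, chromosome 14 from 33580001, plus, and chromosome 5 from 92740001, plus, with 231 each, and chromosome 2 from 172400001, minus, with 223, all at 0 in the 3 P-TEFb libraries. Of the 442, 372 had over 5 counts per position and 12 were also called with distinct positions, against 348 of the 366 higher windows. The fit, in which the single input is assumed to vary like the replicated groups, had 4607 windows at an unadjusted p under 0.05. Its spread rests on the LARP7 and P-TEFb replicates, so that without LARP7 replicate 1 or 2 it called 17 or 16 higher windows, with 322 lower in each, and without P-TEFb replicate 1 it called 1665 in all. DESeq2 called 59 higher and 152 lower.

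Pladienolide B was set against DMSO to see where P-TEFb crosslinking moved when splicing was blocked. Under pla-B the adjacent windows of chromosome 18 from 75530001 and from 75540001, plus strand, held 0.352 and 0.269% of counts against 0.0339 and 0.0322% under DMSO, and chromosome 4 from 140860001, plus, held 0.267% against 0.0558%. The largest ratios lay on chromosome 6 from 100140001 to 100170000, minus, with 178, 147 and 115 counts in its 3 windows against 0, 1 and 1, on chromosome 6 from 67250001, plus, with 354 against 6 (55.6-fold, 95% counting interval 27.3 to 165), and on chromosome 12 from 16550001, minus, with 126 against 2 (51.5-fold, 17.4 to 536). With 0 counts under pla-B stood chromosome 8 from 119130001, minus (339 under DMSO), chromosome 5 from 139890001 and from 139870001, minus (251 and 239), chromosome 13 from 114790001, plus (249), and chromosome 17 from 28600001, minus (235). Neighbouring windows moved together, with r = 0.907 and rho = 0.899 across 16090 adjacent pairs. The longest lower run covered 360 kb of chromosome 13 from 114580001 to 114940000, plus, at 0.139 of DMSO, and the longest higher run 190 kb of chromosome 3 from 78900001 to 79090000, minus, at 3.12-fold. These runs were looked for after the data were seen. Of 22561 windows 27.8% were at least 2-fold higher and 37.4% lower, but 41.9 and 24.3% of the 8199 windows with a summed count of 100 or more and 10105 higher and 4222 lower of 22478 windows of 1 kb. The difference was not tested, as each condition had 1 library. The pla-B library correlated with DMSO at r = 0.142 and with the 3 untreated P-TEFb replicates at r = 0.0475 to 0.0752, while DMSO correlated with those at r = 0.346 to 0.765.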

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

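Among the tests here, the thinning, the splits of the libraries, the strand and repeated-count tests of pla-B, the 4 tests of Rn7sk and the share of mature RNA over every call were chosen only after the results were seen. Flavopiridol and triptolide differed, by the edgeR test of the difference itself, in intron counts of 1218 genes in chromatin total RNA, in exon counts of 5 genes in chromatin poly(A)+ RNA and in those of 1 gene in whole-cell poly(A)+ RNA. In addition 16 genes, among them Pon1, Lrrc69, Kif26b, Neb and Svopl, had introns at least 2-fold lower than 0 h at all 3 times under flavopiridol and at least 2-fold higher at all 3 under triptolide, a difference that was not tested for them as a set. In exon counts of chromatin total RNA 3 genes, Rnu2-10 and 2 gene models without a symbol, went the opposite ways, higher under flavopiridol and lower under triptolide, and that difference was not tested.

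The inhibitors may differ in introns because long genes respond differently. Sequencing depth does not account for it, since thinning all 6 libraries to 3.06 M counts gave 1340 calls (110% of 1218), of which 1141 were shared. Reads of mature RNA are argued against as well, as 25.8% of the 1218 calls lay in the top group, and 48.9% in the bottom group, of 3 equal groups of 9614 genes by the intron to exon ratio of poly(A)+ RNA over that of chromatin total RNA, and 14.2% (33.9% of genes) and 60.7% of the 702 calls with enough counts in all 4 tables. Gene length stays open: across genes, its Spearman correlation with the ratio of flavopiridol to triptolide was -0.145, -0.166 and -0.342 at 1, 3 and 9 h, and genes over 103 kb had 434 calls lower and 53 higher under flavopiridol, so length goes with part of the pattern and cannot be told apart from a difference between the drugs. For introns 1 of the 10 splits of the 6 libraries, the real one, gave 1218 calls and the highest other gave 0, but 10 splits are too few for a share under 0.05.

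Crosslinks of P-TEFb under pla-B might be lost downstream within transcribed stretches. In 71.5% of 2036 covered stretches of at least 60 kb the ratio of pla-B to DMSO was lower in the last part than in the first, against 32.5, 22.1 and 24.5% when P-TEFb replicates 3 and 1 and the input took the place of pla-B. The rule set before the test also asked for about as many lower as higher stretches in replicate 3. Its 32.5% missed that range, so downstream loss stays open. All of these ratios share the DMSO library, and any bias of that library along the strand enters each. A strand swapped in a file is argued against by a correlation with DMSO of -0.00271 on the opposite strand and 0.142 on the same, and repeated counts at single positions by 64.7% of windows past 2-fold with distinct positions, against 65.2% with counts. On the same strand P-TEFb replicate 3 correlated with DMSO at 0.765, and pla-B with the 3 untreated replicates at 0.0475 to 0.0752, so the pla-B library stands apart from all other P-TEFb libraries. With 1 library per condition, the drug and the library, a wrong label included, cannot be told apart.

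Rn7sk may have taken a larger share of chromatin total RNA because Pol III, which transcribes it, is not the target of either inhibitor. Whether a shift towards small RNAs was the whole cause stays open. At 9 h the snoRNA median was 0.0367 of the log2 ratio of Rn7sk under flavopiridol (bootstrap interval -0.173 to 0.186). Under triptolide it was 0.246 (-0.0874 to 0.368). A shift alone would give a ratio near 1 only if snoRNA levels did not themselves change under the inhibitors, which was not measured. The deciding bound was set after these values were seen. At 3 h of flavopiridol the ratio was 0.440 (0.151 to 0.647). A change in library composition stays open, since the log2 ratio of at least 3.78 at 9 h under median-of-ratios scaling rests on 1 factor for every gene of a library, which decides nothing, and no spike-in was used here. Continued Pol III transcription stays open too: Rpph1 had log2 ratios of -0.30 under flavopiridol and 0.64 under triptolide, and Rmrp 0.86 and 1.40.

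For the other tests of groups, 3 of 10 splits gave at least 5 calls in chromatin poly(A)+ RNA and 4 of 10 gave at least 1 in whole cells, which are too few splits for a share under 0.05. The highest other split gave 321 and 542, with flavopiridol 1 h and 9 h and triptolide 1 h on one side. With time as a block this split contrasts the 9 h pair alone. Its calls may reflect a difference between the inhibitors at 9 h or between single libraries, which cannot be told apart. Among the splits that, like the real one, part the libraries of each time, the highest other gave 0 and 1. For chromatin against whole cells 1 of 100 splits, the real one, gave 7222, and the highest other 3701. For chromatin total against poly(A)+ RNA 1 of 100 gave 9609, and the highest other 6846. Both of these other splits swapped 1 condition of the real one. Relabelling within conditions did not reach either real count. Since the library types differ by preparation, the splits cannot tell fraction or selection from preparation.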

How the results depend on the processing

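Among the alternatives, thinning and the intron to exon ratio were added after the data were seen. In the 5 tests of RNA no called gene was called in the opposite direction under an alternative, but several balances of lower and higher turned. RNase A in chromatin total RNA, with 3939 introns lower and 2099 higher and 4831 exons lower and 1976 higher, gave 1390 and 3950 and 2248 and 3205 with a pseudocount of 5, and 4505 and 10301 and 5621 and 16652 with no minimum. Introns at 9 h of triptolide, 3000 lower and 1915 higher, gave 2430 and 2551 under median-of-ratios scaling. Windows under pla-B, 27.8% higher and 37.4% lower, gave 41.9 and 24.3% at a summed count of 100. Chromatin against whole cells, 3497 higher and 3725 lower, gave 4264 and 2709 under table totals, chromatin total against poly(A)+ RNA, 4493 and 5116, gave 7855 and 6458 with no minimum, P-TEFb against LARP7, 27 and 16, gave 1 and 13 in 1 kb windows, and P-TEFb against input, 366 and 442, gave 470 and 15 with distinct positions. Splicing factors had a whole-cell median log2 ratio at 9 h of flavopiridol of -0.26, and 0.27 under median-of-ratios scaling, and other list medians near 0 turned too. Of the values of named genes with a test under all alternatives, 3435 kept direction and side of the threshold, 94 lost the threshold and 61 gained it; without a test 6542 stayed within their counting interval and 1511 moved, 1493 of them under median-of-ratios scaling. Where a count differed by over 1.5 times, the cause was not tested, except that, for the untested ratios, stricter filters and fold limits count fewer genes and no minimum counts more by construction. Scaling by mitochondrial totals was not run, because all those genes were at 0, and table totals are the scaling used for the ratios.

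Flavopiridol against triptolide gave 1218 calls in introns, 3546 with no minimum, 336 without a block and 0 to 1307 without 1 time. In chromatin poly(A)+ RNA 5 calls became 3 under median-of-ratios scaling, 2 under table totals, 56 in DESeq2, 559 with no minimum, 0 without a block and 0 to 341 without 1 time. In whole cells 1 call became 0 under table totals, 53 in DESeq2, 0 in limma-voom, 89 with no minimum, 0 without a block and 0 to 131 without 1 time. Chromatin against whole cells (7222) gave 6502 to 7295 calls without 1 condition and 1206 without a block. P-TEFb against LARP7 (43) gave 74 in DESeq2, 72 with no minimum, 14 in 1 kb and 10 in 100 kb windows, 101 with the replicate block and 5 to 327 without 1 replicate. The replicate numbers did not pair the samples, as deviations of equal numbers correlated at 0.0378 and 0.0322. P-TEFb against input (808) gave 211 in DESeq2, 700 with no minimum (82 higher and 618 lower), 434 in 100 kb windows, 485 with distinct positions and 338 to 1665 without 1 replicate. Windows past 2-fold under pla-B (14713) were 5424 at a summed count of 100.

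Genes at least 2-fold below 0 h at 9 h, with no minimum, were 4911 and 4092 for introns under flavopiridol and triptolide (7127 and 8809 higher, against 1924 and 1915 with the minimum), 9115 and 7585 in chromatin total exons (8744 and 9751 higher), 8922 and 8430 in chromatin poly(A)+ RNA and 9926 and 9653 in whole cells. With a mean of 200 they were 1947 for flavopiridol introns and 2054 and 1961 for chromatin total exons. With a limit of 3-fold they were 1616 and 1788 for introns, 1891 and 1765 for chromatin total exons and 2999 for flavopiridol in whole cells, and under median-of-ratios scaling 3255 for flavopiridol in chromatin poly(A)+ RNA. For mock, no minimum, a mean of 200 and 3-fold gave 1677, 11 and 12 for introns (88 under median-of-ratios scaling), 2600, 13 and 9 for chromatin total exons, 2705, 19 and 12 for chromatin poly(A)+ RNA and 2229, 13 and 6 for whole cells. For RNase A a mean of 200 gave 2513 introns, and in whole cells no minimum gave 1484, a mean of 200 6, a pseudocount of 5 11 and 3-fold 6. The intron share at 0 h was 41.9% over genes with a mean of 50 in both tables.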

Other observations

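The values by gene length, the shuffles and the partial correlations in this part were chosen after the data were seen. Introns of long genes stood lowest soon after flavopiridol. At 1 h, genes over 99.6 kb had a median log2 ratio of intron counts to 0 h of -0.57 under flavopiridol and -0.12 under triptolide, and genes under 13.2 kb had 0.45 and 0.37. Under triptolide the values at 1 h did not follow length throughout, as genes of 46.9 to 99.6 kb had -0.59, below the longest genes, against -0.31 under flavopiridol. At 3 h the longest genes stood at -1.18 and -0.81. Across 9704 genes, which are not independent replicates, the Spearman correlation of length with the ratio was -0.463, -0.503 and -0.472 at 1, 3 and 9 h of flavopiridol and -0.193, -0.299 and -0.208 under triptolide.

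Intron counts that stayed after inhibition may come in part from polyadenylated RNA that keeps introns. Genes with a higher intron to exon ratio in chromatin poly(A)+ RNA at 0 h, taken over that in chromatin total RNA of mock-treated cells, lost less of the ratio in chromatin total RNA, with Spearman correlations across 8130 genes of 0.516 for flavopiridol and 0.675 for triptolide at 3 h. The median change at 3 h was -1.52 in the lowest and -0.50 in the highest group of genes under flavopiridol, and -2.11 and -0.41 under triptolide. The mock library as reference keeps counting noise out of both measures, but the starting ratio of chromatin total RNA enters both. With the poly(A)+ ratios shuffled among genes the correlations had medians of 0.0137 and 0.0388 over 200 shuffles. At an equal starting ratio, the partial correlations of the poly(A)+ ratio with the ratio at 3 h were 0.552 and 0.717.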
